A study of Homo sapiens with 4 samples.

How the data were processed

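Total RNA of 4 organoid samples was extracted with a column kit for small inputs, and libraries were made with a strand-specific poly(A) kit, per the labels' protocols. The 4 libraries fell into 2 groups of 2, grape-like and others, taken from the sample titles. The cell line, the clone label and the time of about 14 days after passage were shared by all 4. Labels do not say outright whether the numbers 1 and 2 stand for separate cultures, so p-values measure the spread between these libraries, which may in part be technical.

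The authors deposited 2 tables over 60230 Ensembl gene identifiers, with 1 column per library. The first holds estimated counts per gene, which the authors did not round: between 39.0% and 51.0% of the values above 0 were whole to within 1e-09. The second holds TPM, which the authors scaled so that each deposited column sums to 1000000. Salmon 1.2.1 and the build GRCh38 are named in the submitters' processing notes. The transcript annotation and the way transcripts were summed to genes are not given in the sources used here. Because the counts come from a method that shares reads between similar transcripts, levels of close paralogs and pseudogenes are less certain than others.

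Symbols were found for 41848 identifiers, from a table of gene names and from GENCODE release 29, which also gave the GRCh38 positions of 57972. All other identifiers were kept without a symbol. Of the identifiers, 34917 were at 0 in every library. Library totals were 22888695 and 18291187 estimated counts for grape-like replicates 1 and 2 and 20576428 and 22912940 for others replicates 1 and 2. For a gene at 0, the limit is 3 counts per library. Intervals on ratios of counts are exact 95% binomial intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

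Estimated counts were rounded to whole numbers and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (robust, two-sided) on a model with the group alone. Genes were kept by the tool's own filter on low counts (10 counts as the minimum and 15 in total), which left 15470, and libraries were scaled with TMM factors (0.963 and 0.990 for grape-like, 1.096 and 0.956 for others). P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Fold changes are grape-like over others, with the standard error taken from the F statistic. The median log2 fold change over all genes was -0.01, and it moved to 0.14 with upper-quartile factors, so that fold changes under that scaling are shifted by that amount.

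Before the data were examined, 41 gene lists were fixed from textbook knowledge of liver, gut, other cell types and stress responses. A list needed 5 measured members, and 38 had them. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, repeated with an estimated correlation and with fry. Single members were also adjusted over the list alone. Estimation of the correlation rests on 2 residual degrees of freedom. A simulated shift of 1 on the log2 scale in 1 of 38 lists gave an adjusted p of 3.59e-09 with the preset correlation. It was 0.79 with the estimated one and 0.107 with fry, and 0 other lists were called. Genes were simulated independently of each other, so this cannot show whether the preset correlation is safe when list members move together. In the real libraries the estimated correlation ran from -0.109 (pluripotency) to 0.874 (mitochondrially encoded transcripts). It was 0.28 for plasma proteins and 0.225 for coagulation and complement.

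Genes named in the text followed a rule that was also fixed beforehand, apart from H19, given as the most abundant gene of 2 libraries, and CLDN18, KRT20 and MUC2 in a figure legend. Its first part took the 8 genes with the smallest p in each direction, with a log2 fold change of at least 1 in size, a mean of at least 5 CPM, no overlap between groups and a proper symbol that is neither mitochondrial nor ribosomal; as no gene passed the threshold, these were filled by unadjusted p. The second part took up to 4 members of each list by p. The third was a fixed set of 16 identity genes, among them ALB, AFP, HNF4A, KRT19, SOX9 and MKI67. Genes named in the closing section outside this rule are marked there as chosen after their values were seen. Values of 3 single genes that the rule would give are not reported here.

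Because the second fraction is what remained after picking, and the titles give both fractions the numbers 1 and 2, a shared number was read as a shared culture. Deviations of same-numbered libraries from their group means had a correlation of 0.327 across genes. Over log2 CPM the correlation was 0.956 between the grape-like libraries, 0.924 between the others libraries, 0.925 and 0.873 within the same-numbered pairs, and 0.881 and 0.878 within the crossed pairs, so that only the pair numbered 1 lay above both crossed values. With 2 pairs these values do not settle the pairing. A model with the replicate number as a block was run beside the model without it, and where it changes a call on a list member or a gene that the report describes, this is said there. The model with the block leaves 1 residual degree of freedom, against 2 without it. Its calls therefore rest largely on variances shared between genes.

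The code was tested on simulated counts drawn from the means, trended dispersions and library sizes of the 15470 genes, with 200 genes changed by known folds of 2, 4, 8 or 16 (50 each). When the numbers carried no difference, edgeR without the block recovered 8%, 80%, 96% and 100% of them, by fold, with 6 false calls, and DESeq2 recovered 10%, 82%, 98% and 100% with 26 false calls. A random difference between numbers was then added, alike in both fractions. Its size was set and not taken from the data, and the dispersions were those of the block fit. In that case edgeR without the block recovered 0% at every fold. With the block edgeR recovered 16%, 92%, 100% and 100% with 11 false calls. DESeq2 without the block recovered 0%, 22%, 90% and 100% with 0 false calls. Each gene was drawn at exactly its trended dispersion, without the spread that real genes have around the trend. The shares recovered therefore need not hold for these libraries. SFN, 9.32-fold higher in the others, had an adjusted p of 0.11 in edgeR without the block.

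Other settings chosen beforehand were RLE factors, library totals alone, upper-quartile factors, DESeq2 1.42.0, limma-voom, a fit that was not robust, no filter on counts, a mean of at least 1 CPM, limma on log2(TPM + 1), on log2(TPM + 0.1) and on genes with a mean TPM of at least 1. The others were a test against a 1.5-fold change, the replicate block in edgeR and in DESeq2, removal of mitochondrially encoded genes and of the 20 most abundant genes, removal of each library in turn, and lists limited to members held by 1 list. Levels of sex-linked marker genes were left out. Figures were drawn with matplotlib 3.10.9.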

Results

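Messenger RNA was measured in hepatocyte organoids grown from ChiPSC18, a commercial human induced pluripotent stem cell line. Such organoids are clusters of hepatocyte-like cells kept in a basement membrane gel. About 14 days after passage, organoids with the outline of a bunch of grapes were picked by eye under a microscope, and the organoids left behind were gathered as a second fraction, called others. The comparison asks which transcripts separate the picked shape from the rest of the culture. Each fraction had 2 libraries, numbered 1 and 2 in both. The grape-like libraries held 22888695 and 18291187 estimated counts and the others libraries 20576428 and 22912940. At these depths 3 counts equalled between 0.133 and 0.166 CPM (counts per 1000000, with library totals scaled by TMM factors). ALB, the gene of serum albumin, was the most abundant gene of both grape-like libraries, with 6.58% and 5.88% of all counts. In both others libraries it was H19, an imprinted non-coding RNA of fetal liver, with 3.04% and 2.53%.

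Genes of secreted liver proteins and of amino acid breakdown stood higher in the grape-like organoids, and genes of gut and duct epithelium, glycolysis and basement membrane stood higher in the others. ALB was at 68367 and 59501 CPM in the grape-like libraries and at 12198 and 16966 CPM in the others, a log2 fold change of 2.13 ± 0.46 (SE, n = 2 per group), or 4.38-fold. AGXT, an enzyme of glyoxylate and alanine metabolism in hepatocytes, had a log2 fold change of 2.36 ± 0.28, and F12, coagulation factor XII, one of 1.93 ± 0.20. On the other side, LAMB3, a laminin chain, had a log2 fold change of -4.40 ± 0.61, the keratin gene KRT19 of duct cells one of -2.37 ± 0.44, and SLC2A1, the glucose transporter GLUT1, one of -3.25 ± 0.39. Of 38 gene lists tested, 10 rose and 8 fell in the grape-like organoids (camera with a preset correlation, adjusted p under 0.05). With the correlation between genes estimated from the 4 libraries, none of the 38 passed, and the smallest adjusted p was 0.43. That version rests on 2 residual degrees of freedom, and it also missed a simulated shift in 1 list (adjusted p = 0.79). Its misses therefore do not show that correlation undid the calls. Urea cycle and bile acid synthesis lost theirs at estimates of -0.041 and -0.003, under the preset 0.01. The 10 lists that rose included the mitochondrially encoded transcripts, whose members moved nearly together (estimated correlation 0.874), so that call is uncertain. Other called lists, apart from urea cycle and bile acid synthesis, also had estimates above the preset value, up to 0.525 for acute phase. Their adjusted p at the preset correlation may be too small.

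**Figure D1:**
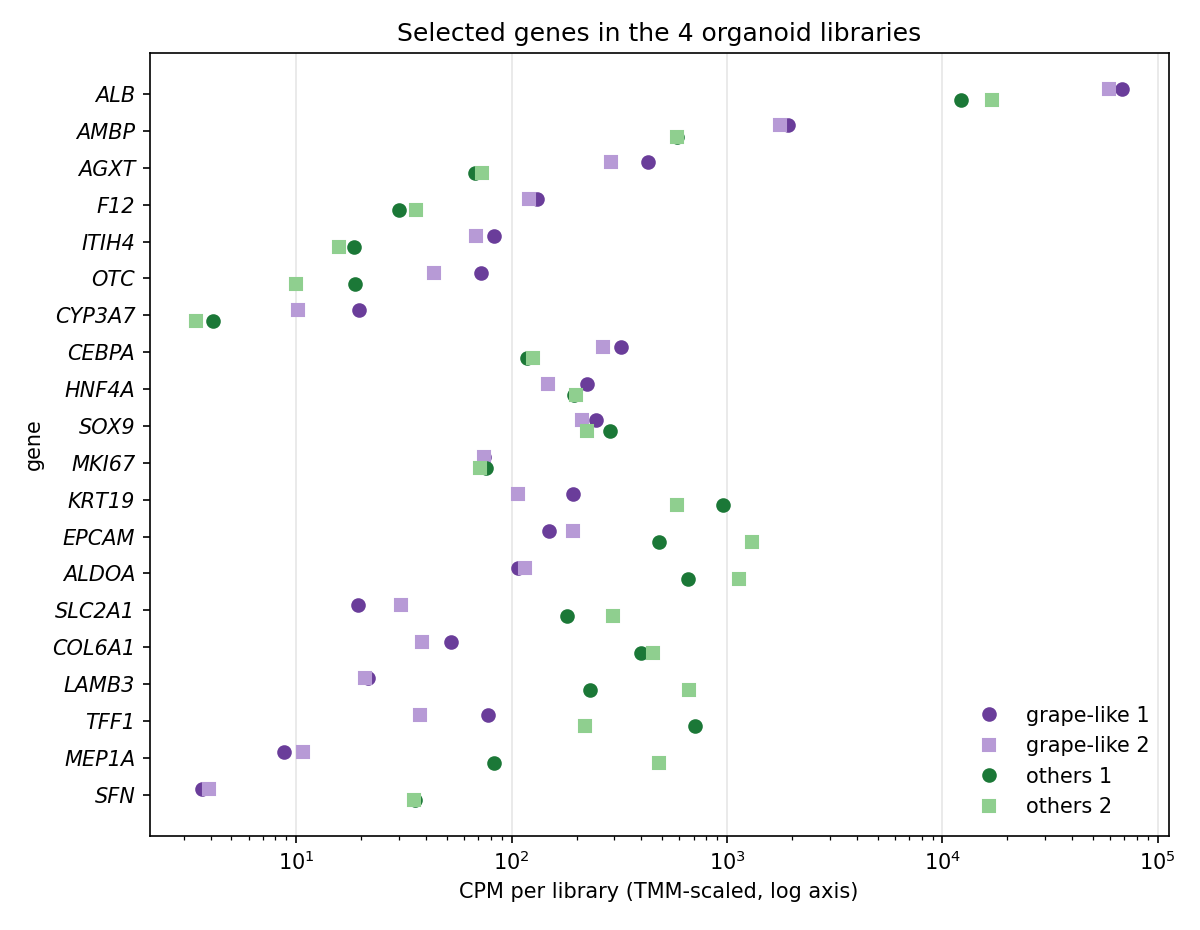
Level of 20 genes in each library, in TMM-scaled CPM on a log axis, with grape-like libraries in purple and others libraries in green (circles, replicate 1; squares, replicate 2). ALB lies between 59501 and 68367 CPM in the grape-like libraries and between 12198 and 16966 CPM in the others, while MKI67 lies between 71.2 and 75.6 CPM in all 4.

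Gene by gene, the unpaired quasi-likelihood test of edgeR called 0 of 15470 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.11. At an unadjusted p under 0.05 it gave 1074 genes higher and 1816 lower in the grape-like organoids, where 774 in all would come by chance. With the library number as a replicate block, which leaves 1 residual degree of freedom, edgeR called 129 genes higher and 300 lower. DESeq2 without the block called 512 higher and 1128 lower. Of the 429 genes called with the block, 393 were also called by DESeq2, each with the same sign. Both fits used the same 4 libraries and the same contrast, so this overlap is not independent support. DESeq2 also made 26 false calls in simulated data without a difference between numbers. In 52.9% of the genes both libraries of one fraction lay above both of the other, against 33.3% on average over the 3 even splits of the libraries. Genes move together, so the share of 1 split can lie far from 33.3% without a difference between fractions, and this was not tested.

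The 8 genes with the smallest p on each side are given as values, since each had an adjusted p of 0.11 without the block (edgeR). With the block their adjusted p lay between 0.0316 and 0.0352. Toward the grape-like side they were MIR122HG, the host transcript of a liver microRNA (GRCh38 chromosome 18, 58446275 to 58453766; log2 fold change 2.10 ± 0.19), HSPA7 (2.73 ± 0.27), ITIH4 (2.14 ± 0.22), F12 (chromosome 5, 177402140 to 177409576), SERPINA10 (1.83 ± 0.20), TFR2 (2.15 ± 0.24), SLC17A9 (1.86 ± 0.21) and KLF15 (1.83 ± 0.21). ITIH4 and SERPINA10 encode plasma proteins made by the liver, TFR2 a transferrin receptor of hepatocytes, and KLF15 a transcription factor of amino acid metabolism. HSPA7 shares most of its sequence with a neighbouring heat shock gene, so its level is uncertain. Toward the others side they were SFN, the epithelial protein stratifin (chromosome 1, 26863138 to 26864457; -3.22 ± 0.22), KCNK6 (-3.03 ± 0.23), C1orf116 (-2.81 ± 0.22), MALL (-2.53 ± 0.19), C15orf48 (-4.44 ± 0.35), B3GNT7 (-3.85 ± 0.31), GALNT3 (-3.04 ± 0.26) and COL6A1, a chain of collagen VI (chromosome 21, 45981737 to 46005050; -3.23 ± 0.28). SFN was at 3.63 and 3.93 CPM in the grape-like libraries and at 35.5 and 35.1 CPM in the others. GALNT3 and B3GNT7 encode enzymes of protein glycosylation. Of the rest of the 97 named genes that were followed through the alternative settings, 30 also passed over all genes with the block (adjusted p from 0.0316 to 0.0482). They were F13B, AGXT, HAL, TDO2, AMDHD1, SAA4, FGL1, OTC, SLCO1B3, PLIN5, SULT2A1 and GYS2 on the grape-like side and CYP3A4, KRT19, UGT2B17, SLC5A1, SI, TFF1, TFF2, SLC2A1, ALDOA, PKM, TJP3, EZR, CLDN7, ITGB6, LAMB3, BMP4, RNF43 and PTPN14 on the others side.

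Plasma proteins and apolipoproteins rose as a list (29 genes, median log2 fold change 1.52, camera adjusted p = 2.54e-17; adjusted p = 0.43 with an estimated correlation). Adjusted over the list alone, 17 of the 29 members rose and 0 fell. Over all genes 0 passed, and 4 did so with the replicate block. With the block 19 rose and 0 fell over the list alone. HPX, the haem carrier hemopexin, had a log2 fold change of 2.18 ± 0.35, AMBP 1.65 ± 0.27 and APOE 1.53 ± 0.27. Some abundant members did not pass in either way: SERPINA1 (0.39 ± 0.47), TTR (0.68 ± 0.71) and APOA1, which was at 1780 and 1694 CPM in the grape-like libraries and at 834 and 3952 CPM in the others. Without others replicate 2 the log2 fold change of APOA1 turned from -0.46 to 1.09, and without grape-like replicate 2 that of TTR turned to -0.10. Within both same-numbered pairs TTR and SERPINA1 were higher in the grape-like library, and with the block the values were 0.76 ± 0.29 (adjusted p = 0.214) and 0.43 ± 0.43 (adjusted p = 0.602). Coagulation and complement rose as well (32 genes, median 1.39, adjusted p = 1.47e-22; adjusted p = 0.43 with an estimated correlation). Of its members 22 rose when adjusted over the list alone, 0 over all genes and 8 with the block. Over the list alone 28 rose with the block. Examples were F13B (1.99 ± 0.26) and CPB2, an inhibitor of clot breakdown (1.71 ± 0.28). These lists moved together with the fall of the intestinal list described further on.

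Amino acid catabolism had the highest median of the lists that rose (21 genes, median 1.65, adjusted p = 1.97e-18; adjusted p = 0.43 with an estimated correlation). All 21 fold changes were above 0, and 15 members rose when adjusted over the list alone, 0 over all genes and 7 with the block. Over the list alone 18 rose with the block. HAL and AMDHD1, enzymes of histidine breakdown, had log2 fold changes of 2.34 ± 0.30 and 2.43 ± 0.36, and TDO2, which opens the tryptophan ring, one of 2.39 ± 0.33. Urea cycle and ammonia handling rose (12 genes, median 0.79, adjusted p = 4.39e-05; adjusted p = 0.43 with an estimated correlation), with 4 members rising over the list alone, 0 over all genes and 1 with the block. The 4 included GLS2, the liver glutaminase (1.98 ± 0.30), ASS1 (190 and 148 CPM against 65.8 and 80.9 CPM) and OTC (4.01-fold, log2 SE 0.43). The acute phase list rose too (17 genes, median 1.37, adjusted p = 3.93e-05; adjusted p = 0.559 with an estimated correlation). Within it, 6 members rose over the list alone, 0 over all genes and 2 with the block. The 6 included SAA4 (2.69 ± 0.37), FGL1 (684 and 585 CPM against 131 and 186 CPM) and CP, the copper carrier ceruloplasmin (1.36 ± 0.28). With the block 8 rose and 1 fell over the list alone. Without grape-like replicate 1 the acute phase list no longer passed (adjusted p = 0.173, against 7.88e-19 at the lowest of the alternatives). All 3 lists rose beside the fall of the intestinal list (median -5.13).

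Bile acid synthesis rose as a list (16 genes, median 0.89, adjusted p = 0.000793; adjusted p = 0.43 with an estimated correlation), although 0 of its members passed over the list alone. With the block 6 rose over the list alone and 0 over all genes. AKR1C4 (1.55 ± 0.31) and CYP39A1 (1.53 ± 0.36) had the smallest p, and both were among the 6 (adjusted p = 0.0321). Lipogenesis (20 genes, median 0.57, adjusted p = 0.00642) and cholesterol synthesis and uptake (24 genes, median 0.38, adjusted p = 0.00357) rose by less. Both had an adjusted p of 0.559 with an estimated correlation. In lipogenesis 1 member rose over the list alone, PLIN5, a coat protein of lipid droplets (2.27 ± 0.31), and GPAM, the enzyme at the start of glycerolipid synthesis, had 1.17 ± 0.28. In the cholesterol list 0 did, and HSD17B7, an enzyme of cholesterol synthesis, had 0.83 ± 0.20. Hepatobiliary transporters rose as a list (22 genes, median 0.53, adjusted p = 0.00502; adjusted p = 0.559 with an estimated correlation) with members on both sides. Over the list alone 8 rose and 3 fell, over all genes 0 passed, and with the block 3 rose. The uptake carrier SLCO1B3 (2.33 ± 0.39), the exporter ABCC4 (1.28 ± 0.23) and SLC47A1 (1.63 ± 0.35) rose, while ABCG2, a drug exporter also present in gut, fell by 5.31 on the log2 scale (SE 1.14). ABCG2 was at 41.7 and 334 CPM in the others libraries, and leaving out 1 library put its log2 fold change between -6.16 and -3.11. With the block 10 rose and 2 fell over the list alone, and ABCG2 did not pass (adjusted p = 0.065). Without others replicate 1 neither the transporter list (adjusted p = 0.791, lowest of the alternatives 3.2e-05) nor lipogenesis (0.212, lowest 0.00107) passed. These 4 lists, too, rose beside the fall of the intestinal list.

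Mitochondrially encoded transcripts passed as higher in camera with the preset correlation (13 genes, median 0.76, adjusted p = 0.00159, and 0.675 with an estimated correlation). Over the list alone 0 single members passed, again beside the fall of the intestinal list. The estimated correlation between members was 0.874, so the 13 genes moved nearly as 1. The preset correlation is far below that value, so this call cannot show that the list rose. Part of this doubt holds for other called lists. The estimate was 0.525 for acute phase, 0.51 for gastric and pancreatic, 0.293 for hypoxia and glycolysis and 0.28 for plasma proteins. Their adjusted p at the preset correlation may be too small. MT-ATP8 had a log2 fold change of 0.90 ± 0.40 and MT-ND3 one of 0.82 ± 0.39, and without 1 library they lay between 0.36 and 1.30 and between 0.38 and 1.15. These genes took 7.41% and 4.94% of the counts in the grape-like libraries and 4.80% and 3.60% in the others. The call was lost without grape-like replicate 1 (adjusted p = 0.152, lowest of the alternatives 1.66e-07).

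**Figure D2:**
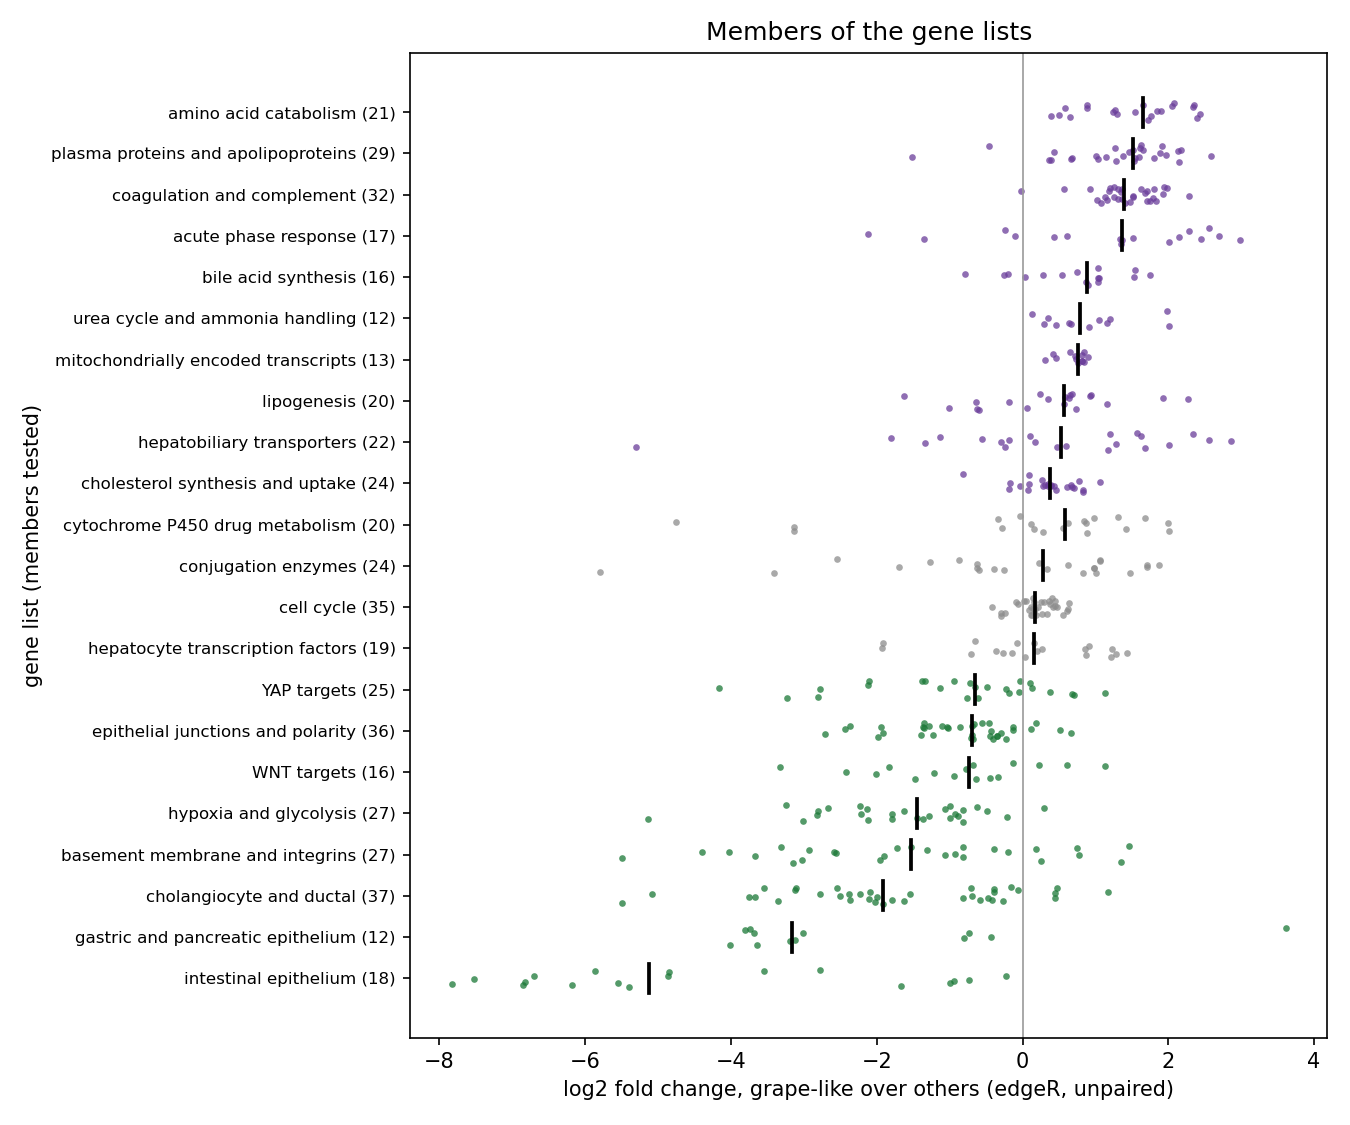
Log2 fold change of grape-like over others (edgeR, unpaired) for each tested member of 22 gene lists, with a black bar at the median: purple, the 10 lists that rose; green, the 8 that fell; grey, 4 lists without a call. Medians run from 1.65 for amino acid catabolism to -5.13 for intestinal epithelium.

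Intestinal epithelium had the lowest median of all lists (18 genes, median -5.13, adjusted p = 3.22e-11; adjusted p = 0.43 with an estimated correlation). All 18 fold changes were below 0, and 10 members fell when adjusted over the list alone, 0 over all genes and 3 with the block. The fall was not uniform, since some members were higher in the grape-like library of the pair numbered 2, as given in the closing section. Sucrase-isomaltase, SI, had 3 counts over both grape-like libraries and 258 over both others libraries, a ratio of 77.7 after scaling (exact 95% interval 26.3 to 379, for counting error only). FABP2, the fatty acid binding protein of enterocytes, was at 1.54 and 0.774 CPM in the grape-like libraries and at 56.6 and 216 CPM in the others (log2 fold change -7.53 to -5.56 without 1 library). MEP1A, a brush border protease, had a log2 fold change of -4.86 ± 0.97 and ISX, an intestinal transcription factor, one of -5.54 ± 1.08. Others replicate 2 held more of both than others replicate 1 (482 against 82.9 CPM and 130 against 23.7 CPM), and without it the values were -3.06 and -3.82. With the block 7 members fell over the list alone, and ISX did not pass (adjusted p = 0.0923). The gastric and pancreatic list fell (12 genes, median -3.16, adjusted p = 0.0348; adjusted p = 0.709 with an estimated correlation) with 0 members passing over the list alone. With the block 9 fell and 1 rose over the list alone, and 2 fell over all genes. The trefoil peptide genes TFF1 and TFF2 had log2 fold changes of -3.01 ± 0.73 and -3.74 ± 1.34, and each had an adjusted p of 0.0316 with the block. Without 1 library they lay between -3.63 and -1.94 and between -5.96 and -2.17. The call on the gastric list was lost without others replicate 1 (adjusted p = 0.898), without grape-like replicate 2 (0.169) and under 5 other settings (0.0664 to 0.289), and its lowest adjusted p over the alternatives was 1.59e-08.

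**Figure D3:**
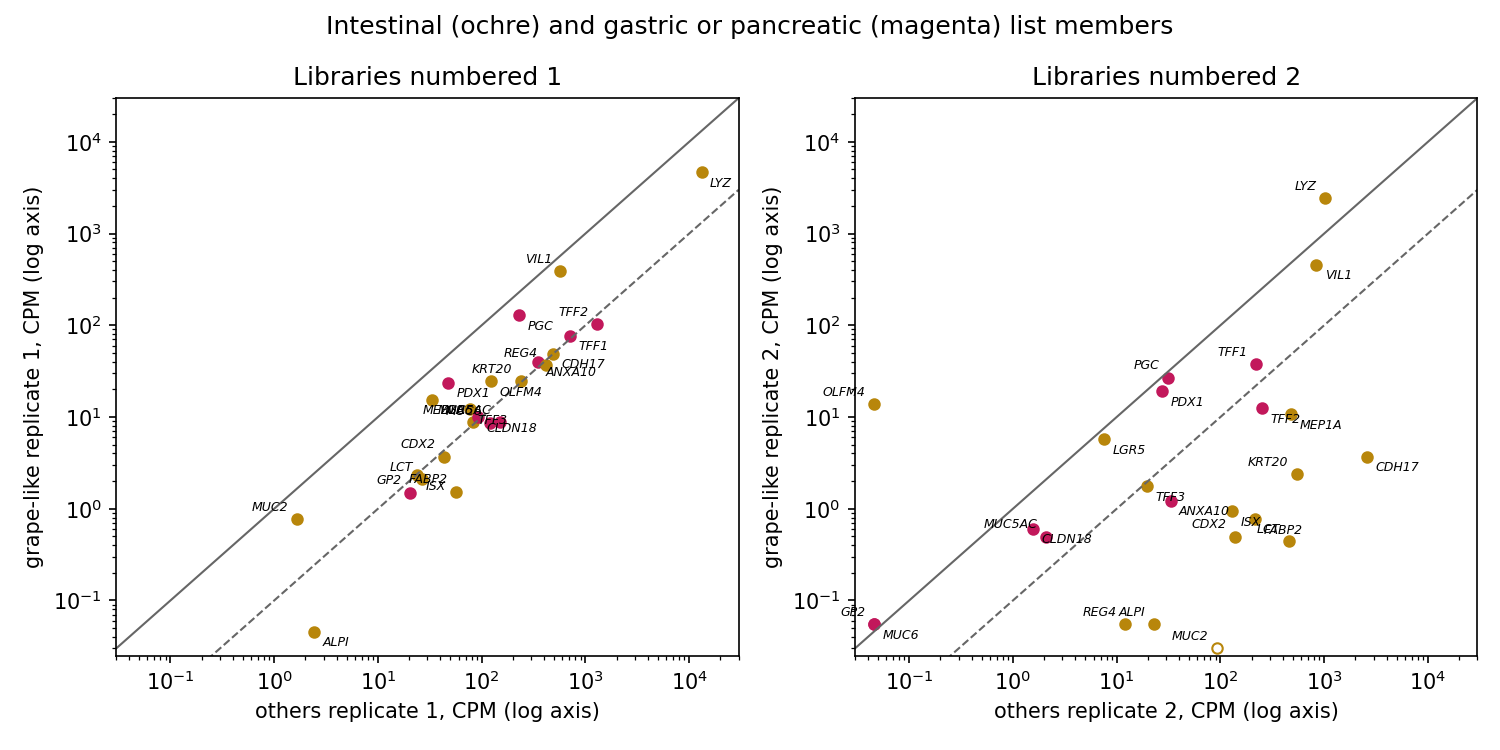
Level in CPM of 24 members of the intestinal list (ochre) and of the gastric and pancreatic list (magenta), others on the x axis and grape-like on the y axis, both log axes, for the libraries numbered 1 (left) and 2 (right). The solid line marks equal levels and the dashed line a grape-like level at 10% of the others level; the open circle is MUC2, at 0 in grape-like replicate 2. Many genes lie near the dashed line on the left, and on the right some lie far below it and some above: KRT20 is at 10.4% and 0.435%, TFF1 at 10.9% and 17.2%, and CLDN18 at 10.9% and 39.1%.

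Ductal markers fell as a list (37 genes, median -1.91, adjusted p = 2.58e-08; adjusted p = 0.43 with an estimated correlation). Over the list alone 12 members fell and 0 rose (15 and 0 with the block), over all genes 0 passed, and with the block 5 fell. The 12 included KRT19 (adjusted p = 0.0333 with the block), EPCAM (-2.39 ± 0.55), the epithelial transcription factor ELF3 (-2.09 ± 0.37) and SLC5A1, the sodium-coupled glucose carrier of gut and duct (-5.08 ± 0.79). KRT7 was at 30.5 and 4.98 CPM in the grape-like libraries and at 106 and 47.1 CPM in the others. With the block KRT7 passed over the list alone (adjusted p = 0.0166). Leaving out 1 library put KRT7 between -3.94 and -1.33, EPCAM between -2.94 and -1.48 and SLC5A1 between -6.90 and -4.34. SLC5A1 had 15 and 2 counts in the grape-like libraries, so the size of its fall is uncertain. SOX9, a ductal transcription factor, had a log2 fold change of -0.15 ± 0.24 and SPP1, the gene of osteopontin, one of 0.45 ± 1.90. Neither differed by more than its error, and both signs turned under some alternatives. Epithelial junctions and polarity fell (36 genes, median -0.69, adjusted p = 8.7e-08; adjusted p = 0.559 with an estimated correlation). Within this list 7 members fell over the list alone, 0 over all genes and 5 with the block, and with the block 15 fell over the list alone. TJP3, a tight junction protein, had a log2 fold change of -1.98 ± 0.20, EZR, the membrane linker ezrin, one of -2.44 ± 0.26 and CLDN7 one of -2.37 ± 0.45. Both lists fell beside the intestinal one, and gut epithelium also uses many of their genes.

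Hypoxia and glycolysis genes fell (27 genes, median -1.45, adjusted p = 6.77e-15; adjusted p = 0.43 with an estimated correlation). Of these, 14 fell over the list alone, 0 over all genes and 9 with the block. Over the list alone 20 fell with the block. SLC2A1 was at 19.4 and 30.7 CPM in the grape-like libraries and at 180 and 296 CPM in the others. ALDOA, a glycolytic aldolase, had a log2 fold change of -3.02 ± 0.37 and PKM, pyruvate kinase, one of -1.79 ± 0.24. Basement membrane and integrins fell (27 genes, median -1.54, adjusted p = 3.85e-07; adjusted p = 0.559 with an estimated correlation). Here 13 members fell and 1 rose over the list alone, 0 passed over all genes, and with the block 3 fell and 1 rose. With the block, 3 rose and 12 fell over the list alone. ITGB6, an epithelial integrin, had a log2 fold change of -2.55 ± 0.25, and LAMB3 was at 21.5 and 20.8 CPM against 231 and 664 CPM, which put its log2 fold change between -4.99 and -3.42 without 1 library. The 1 that rose over the list alone without the block was COL18A1, a basement membrane collagen that hepatocytes make (1.36 ± 0.24). Both lists fell beside the intestinal list (median -5.13) and the ductal list (median -1.91).

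WNT targets fell (16 genes, median -0.73, adjusted p = 0.00293; adjusted p = 0.559 with an estimated correlation), with 5 members falling over the list alone, 0 over all genes and 4 with the block. Over the list alone 7 fell with the block. BMP4 (-2.01 ± 0.27), TNFRSF19 (-3.33 ± 0.56, and -4.27 to -2.78 without 1 library) and RNF43, a negative regulator of WNT receptors (-1.48 ± 0.30), were among the 5. This call was lost without others replicate 1 (adjusted p = 0.264), without grape-like replicate 2 (0.0841) and on TPM values limited to genes with a mean of 1 or more (0.0556), and its lowest adjusted p over the alternatives was 7.64e-05. YAP targets fell (25 genes, median -0.65, adjusted p = 0.00865; adjusted p = 0.585 with an estimated correlation), with PTPN14 falling (-1.38 ± 0.24) and NT5E rising (1.14 ± 0.21) over the list alone, where the block gave 3 falling and 1 rising. Without others replicate 2 the YAP list did not pass (adjusted p = 0.426, lowest of the alternatives 4.12e-05). The WNT and YAP lists also fell beside the intestinal and ductal ones.

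The cytochrome P450 list of drug metabolism did not pass (20 genes, median 0.59, camera adjusted p = 0.158), and over the list alone 4 members rose and 2 fell (5 and 2 with the block). CYP3A7, the fetal CYP3A form, rose (1.99 ± 0.42), while CYP2S1, an epithelial form, and CYP2B6 fell by 3.14 and 4.75 on the log2 scale (SE 0.50 and 0.98), with values from -3.63 to -2.42 and from -6.52 to -3.81 without 1 library. With the block CYP2B6 did not pass over the list alone (adjusted p = 0.102). CYP3A4, the main adult form, was at 2.68 and 0.166 CPM in the grape-like libraries and at 20.9 and 4.48 CPM in the others, with a log2 fold change of -3.13 ± 1.38 (adjusted p = 0.323, and 0.047 with the block), which lay between -6.21 and -1.66 without 1 library. Reads of CYP3A4 and CYP3A7 can be hard to part, as the genes are close relatives. Conjugation enzymes did not pass (24 genes, median 0.28, adjusted p = 0.233, and 0.0321 without grape-like replicate 2), with 6 members rising and 3 falling over the list alone, and 9 and 5 with the block. UGT2B4 (1.70 ± 0.29) and SULT2A1 (1.88 ± 0.35) rose. UGT2B17 fell by 5.80 on the log2 scale (SE 0.79, and -7.30 to -5.13 without 1 library). It had 17 and 3 counts in the grape-like libraries, so the size of its fall is uncertain. The UGT2B genes are also close relatives. Gluconeogenesis and glycogen did not pass (15 genes, median 0.46, adjusted p = 0.237), with 3 members rising and 2 falling over the list alone (4 and 1 with the block). GYS2, liver glycogen synthase, rose (2.26 ± 0.36), while PCK1, an enzyme of liver that gut also uses, fell by 2.31 (SE 0.53, and -2.95 to -1.71 without 1 library) but did not pass with the block (adjusted p = 0.075 over the list alone).

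Hepatocyte transcription factors did not pass (19 genes, median 0.15, adjusted p = 0.151), but did so without others replicate 2 (adjusted p = 0.00989). Over the list alone CEBPA (1.28 ± 0.22), MLXIPL (1.22 ± 0.28), FOXA3 (0.86 ± 0.20) and PROX1 (0.91 ± 0.21) rose and 0 fell, and with the block 7 rose and 3 fell. HNF4A, a factor shared by hepatocytes and gut epithelium, was at 225 and 147 CPM in the grape-like libraries and at 195 and 199 CPM in the others (-0.08 ± 0.28), and its sign turned with upper-quartile factors (0.07) and without grape-like replicate 2 (0.19). The hepatoblast list did not pass (18 genes, median 0.39, adjusted p = 0.0953, and 0.00431 when limited to members held by 1 list), with 0 members passing over the list alone and, with the block, 2 rising, CYP3A7 among them, and 1 falling, TBX3 (adjusted p = 0.0265 for both). AFP, the fetal counterpart of albumin, was at 2708 and 7846 CPM in the grape-like libraries and at 1054 and 4502 CPM in the others, so its difference between numbers exceeded that between fractions. It was higher in the grape-like library of both numbers, with a log2 fold change of 1.08 ± 0.38 with the block (adjusted p = 0.185). The unpaired value of 0.92 ± 0.88 turned to -0.03 without grape-like replicate 2. Of 35 cell cycle genes 0 passed over the list alone, and the list did not pass (median 0.17, adjusted p = 0.0748). It did pass without others replicate 1 (adjusted p = 4.76e-05), without grape-like replicate 2 (0.0464) and with limma-voom (0.0324). MKI67, a marker of dividing cells, had a log2 fold change of 0.02 ± 0.18, with a sign that turned under library totals alone (-0.05).

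The mesenchymal and stellate list did not pass (16 genes, median -0.25, adjusted p = 0.513), but did so, as lower, without others replicate 1 (adjusted p = 0.00145). In it COL6A1 fell and CDH2, a cadherin of hepatocytes as well as of mesenchyme, rose (1.12 ± 0.21) over the list alone, where the block gave 2 rising and 3 falling. COL1A1 (-0.90 ± 0.23) did not pass (adjusted p = 0.0624 over the list alone, and 0.042 with the block), and VIM (0.18 ± 0.53) turned to -0.41 without others replicate 1. Of the endothelial, the macrophage and blood, and the metallothionein lists, 3, 4 and 2 members were measured, which was too few for a list test. Adjusted p was 0.393 for fatty acid oxidation, 0.974 for neural genes, 0.878 for pluripotency, 0.252 for NOTCH targets, 0.711 for TGF-beta targets, 0.151 for the unfolded protein response and 0.611 for p53 targets. It was 0.878 for the interferon response, 0.611 for inflammatory cytokines, 0.0646 for the oxidative stress response, 0.945 for immediate early and heat shock genes, 0.606 for histones and 0.887 for cilia. Of these, 4 passed under some settings: TGF-beta targets without others replicate 2 (0.00548), the unfolded protein response without others replicate 1 (0.00271), inflammatory cytokines without grape-like replicate 1 (0.00577) and the oxidative stress response under 5 settings (0.0114 to 0.0458).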

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

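The removal of an estimated share of others replicate 1 from grape-like replicate 1 and the limits varied for that share were chosen after the data were seen, and all other alternatives were planned. The counts of 0 genes higher and 0 lower (edgeR, unpaired; 1074 and 1816 at an unadjusted p under 0.05) stayed at 0 under most settings. They rose to 512 and 1128 with DESeq2, to 129 and 300 with the replicate block, to 487 and 1198 with the replicate block in DESeq2, and to 247 and 454 without a filter on counts, where 25306 genes were tested. After removal of the estimated share they were 0 and 20, and 157 and 521 with the block added. Leaving out 1 library at a time gave 0 to 48 genes higher and 0 to 528 lower; the calls came without others replicate 1, and the lone library of a fraction was then assumed to vary like the other fraction. The cause of these differences was not tested. In simulated data edgeR without the block lost every call once a random difference between numbers was added. The size of that difference was not taken from these libraries, so the simulation cannot show that it explains the 0 calls here.

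The 10 lists that rose and 8 that fell became 0 and 0 with an estimated correlation (smallest adjusted p 0.43) and 0 and 0 with fry (smallest 0.194), while fry gave 25 lists with members changed in either direction. The estimated correlation and fry also missed the simulated shift in 1 list (adjusted p 0.79 and 0.107). Without 1 library the counts were 8 to 13 lists higher and 7 to 10 lower. The replicate block called the same 18 lists. Apart from the estimated correlation and fry, 11 of the 18 lists passed under every alternative, and 9 lists without a call passed under at least 1. Of the genes named in the text, 97 were followed through the settings. H19, CLDN18, KRT20, MUC2, MUC5AC, MUC6, LCT, CDH17, OLFM4 and LYZ were not. Of the 97 genes, 0 passed over all genes in edgeR without the block, 46 with it and 82 in DESeq2. Under every setting run, 89 of them kept their sign. MKI67 turned to -0.05 with library totals, -0.19 on log2(TPM + 1) with and without the filter, and -0.21 on log2(TPM + 0.1), HNF4A to 0.07 with upper-quartile factors, and SPP1 to -0.32 with limma-voom, -0.19 and -0.51 on TPM, -0.16 with the replicate block (also after removal of the share) and -0.29 with the block in DESeq2. Without 1 library the log2 fold change was -0.42 to 0.19 for HNF4A, -4.57 to 3.44 for SPP1, -0.03 to 2.36 for AFP, -0.10 to 1.75 for TTR, -0.29 to 0.01 for SOX9, -0.41 to 1.18 for VIM and -1.20 to 1.09 for APOA1. At these depths 3 counts equalled at most 0.166 CPM, and lower levels could not be told from 0.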

Other observations

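Calls adjusted over a list alone were planned. The comparisons of others libraries and the tests of explanations in this part were chosen after the values they concern had been seen, and the gut genes named here outside the lists' smallest p-values were picked from those values. Single genes moved in lists that did not pass as a whole. Adjusted over the list alone, MAP2, a microtubule protein, rose (log2 fold change 1.67 ± 0.26), the stem and epithelial factor KLF4 fell by 2.83 (SE 0.41), and in the interferon list 3 members fell, among them ISG20 by 2.04 (SE 0.32), and 1 rose, IFIT1 (1.06 ± 0.21). Over all genes none of these passed in edgeR without the block. TBX3, a target of WNT signalling in liver, stood at 75.8 and 63.6 CPM in the grape-like libraries and at 140 and 184 CPM in the others.

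The others fractions of the numbered pairs differed from each other in their gut genes. MUC5AC and MUC6, mucins of the stomach, were at 150 and 121 CPM in others replicate 1 and at 2.06 and 0.0457 CPM (1 count) in others replicate 2. LCT, CDH17 and MUC2, genes of the intestine, were at 26.3, 484 and 1.64 CPM in others replicate 1 and at 454, 2599 and 92.2 CPM in others replicate 2. OLFM4, a gut stem cell gene, was at 24.7 and 13.7 CPM in the grape-like libraries and at 122 and 0.0457 CPM (1 count) in the others. LYZ, also in the intestinal list, was at 4689 and 2416 CPM in the grape-like libraries and at 13158 and 1028 CPM in the others. In the pair numbered 2 both were thus higher in the grape-like library. With 1 library for each fraction and number, these differences were not tested. Of the 3 ways to split the libraries evenly, the split by fraction gave 2890 genes at an unadjusted p under 0.05 in edgeR and the highest of the other splits, by number, gave 477. DESeq2 called 1640 genes on the split by fraction, 111 on the split by number and 6 on the crossed split; 3 splits are too few for a share under 0.05.

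Grape-like replicate 1 held transcripts of others replicate 1 that were low in grape-like replicate 2. Over 97 genes at 20 CPM or more in others replicate 1 and under 2% of that level in grape-like replicate 2, it held a median of 10.4% of the others level (quartiles 8.07% and 13.7%, a ratio of 1.7), against 0.357% over 57 such genes in the pair numbered 2. Material of the others fraction in the picked sample would give a share near 1 value over so many genes. The median was 8.22% over the 12 genes in the intestinal and gastric lists and 11.4% over the 79 in no list. Some genes lay well below it, among them FABP2 (2.73%) and UGT2B17 (0.772 CPM in grape-like replicate 1 against 36.3 CPM in others replicate 1). Other limits on level moved the median between 10% and 12%. Reads spreading to every library at a like rate are argued against, since over 21 genes under 2% of that level in others replicate 2, grape-like replicate 2 held 0.029 times the median percent of grape-like replicate 1. Grape-like organoids that themselves contain such cells cannot be told apart from a few other organoids picked along, because there was 1 library for each fraction and number. Of the 18 intestinal genes measured, 9 were at 1 CPM or more in both grape-like libraries and 4 were also in another list.

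The 48 liver secretory genes compared here were higher in the grape-like libraries of both numbers (lowest log2 fold change 0.31 and 0.06). They had a mean of at least 20 CPM in the grape-like libraries, a filter that favours genes high there. APOA1, left out with the apolipoproteins, was lower in grape-like replicate 2 than in others replicate 2 (1694 against 3952 CPM). A candidate explanation is that the others hold the same hepatocytes thinned by cells without liver transcripts. That would lower all such genes by 1 factor, with no relation between pairs in how far each gene moved. Over 48 genes of the plasma protein and coagulation lists, without apolipoproteins, the log2 fold changes of pair 1 (median 1.88, SD 0.55) and pair 2 (median 1.30, SD 0.46) were related across genes (Spearman rho 0.53, permutation p = 0.00013; Pearson r 0.53, permutation p = 0.00013; r 0.50 without the 2 genes farthest from the median), which argues against thinning as the whole cause, though genes are not independent replicates and this was the 1 relation computed. Over 4 library scalings the median of the plasma protein list lay between 1.46 and 1.69, and that of all genes between -0.09 and 0.14. The scalings differ by little, so this shows only that the choice among them did not make the difference. Thinning by cells that make some of these transcripts remains open.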
